A study of Homo sapiens with 6 samples.

How the data were processed

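Total RNA from 6 samples of the human embryonic stem cell line H9 was hybridised to Affymetrix human gene arrays, with 1 array per sample. Per the labels, H9 cells were transduced with a lentiviral vector, sorted for eGFP and a pluripotency surface antigen, plated as single cells on mouse embryonic fibroblast feeders, and grown as clones in conditioned medium with 8 ng/ml of bFGF. The 3 groups of 2 arrays carried the eGFP vector alone (CTRL), H2A.X with the substitution S139E (gamma_ON), or H2A.X with T136A and S139A (gamma_OFF). Groups and replicate numbers were taken from the sample descriptions. The labels do not say whether replicates 1 and 2 of a vector come from separate clones or separate cultures, so p-values measure the spread between these samples, which may be technical.

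The deposited values are log2 expression levels per array row, 1 column per sample; the submitters' processing notes name RMA, which corrects background, normalizes and summarizes probes, and Partek 6.6. The order and options of these steps, the genome build and the annotation are not given in the sources used here. The log2 unit was read from the values, whose medians per array lay between 6.11 and 6.25. The number of arrays limits the precision, and no raw scanner values were analysed here.

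The value table held 53617 rows. A probe table from the platform annotation paired 16098 rows with 1 gene symbol each, 0 rows with several, and left 37519 rows unnamed here. All 16098 gene identifiers matched the RefSeq gene table of the assembly GRCh38.p14, and 0 symbols changed. Of the 779 genes with several rows, the row with the highest mean over the 6 arrays was used, which left 14884 genes. H2AX itself and all 44 listed replication-dependent histone genes had no named row, so the level of the transgene's own gene was not analysed here.

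Differences were tested with limma 3.58.1 (lmFit and eBayes, without trend or robust fitting) in R 4.3.3. A single fit over all 6 arrays had 3 residual degrees of freedom and 6.05 prior degrees of freedom, and gave 3 two-sided contrasts and a moderated F test over the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. All adjusted p-values for genes are limma's. A two-sided exact test of 2 against 2 arrays cannot go below p = 0.333, so none was used.

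Gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The 30 lists covered pluripotency, germ layers and lineages, signalling targets, stress and damage responses, cell cycle, chromatin and cell types that a culture could hold, and 29 had at least 5 measured members. Each list was tested with limma's camera, which compares the members with all other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation and limma's fry were run beside it. For the trophoblast and amnion list the estimate was -0.00312, under the preset 0.01. Its unadjusted camera p for gamma_ON against CTRL still rose from 0.0147 to 0.0834. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. For each comparison the rule takes the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes whose groups do not overlap, leaving out symbols of uncharacterised loci, several small RNA families, olfactory receptors and antisense transcripts. It also takes up to 4 members of each list past its threshold and up to 2 members of each list with a called member, and always POU5F1, NANOG and SOX2. The text gives values for part of these list members. Members outside this rule that stand beside a count (APOA2, CXCR4, VRTN and LCK for gamma_ON against CTRL, TTR, FGB and GATA6 for gamma_OFF against CTRL, MIXL1, RIPPLY2, FST, NODAL and LEFTY1 for gamma_ON against gamma_OFF, and the genes that only the closing section names) were chosen after their values were seen, and so were their tests with arrays left out.

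The simulation of unchanged groups took 100 draws of values with the moderated variance of each gene, and set both unchanged groups against the same simulated controls. The scripts were tested on simulated data for gamma_ON against CTRL with 14884 genes: 93.0% of 100 genes changed by 1 log2 unit and 100% of 100 genes changed by 2 log2 units were recovered, with 15 false calls among 208, and 0 calls were made in an unchanged comparison. A simulated list shifted by 0.5 was called (camera adjusted p = 1.4e-34, and 0.0232 with an estimated correlation), with 0 other lists called. The simulated genes were independent and varied alike in every group, whereas the measured mesenchymal list had an estimated correlation of 0.69. These checks therefore do not show how often genes or lists are falsely called in the measured data. Alternatives varied the spread model, the arrays in the fit, a filter on dim genes, the rows of a gene, normalization, array weights, the threshold and the replicate number as a block, and left out each array in turn, where the lone array of its group is assumed to vary like the others. Rescaling each array to the same slope on the mean of the 6 arrays, and setting each mutant group against its own CTRL array, were added after the data were seen. Figures and summaries were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.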

Results

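Gene expression was profiled in clones of H9, a widely used human embryonic stem cell line, that carried 1 of 3 lentiviral vectors. H2A.X is a histone H2A variant whose phosphorylated form, γH2A.X, marks DNA double-strand breaks. The gamma_ON clones carried H2A.X with S139E, in which a glutamate stands in for the phosphorylated serine. The gamma_OFF clones carried H2A.X with T136A and S139A, whose alanines cannot be phosphorylated. CTRL clones carried the eGFP vector alone. The series title names a role of γH2A.X in how human pluripotent cells renew themselves and differentiate. Each group had 2 arrays.

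The CTRL arrays and the gamma_ON arrays each resembled their own replicate most, while gamma_OFF replicate 1 lay nearer gamma_ON replicate 2 than its own replicate. Across 14884 genes, which are not independent replicates, Pearson's r was 0.994 between the CTRL arrays, 0.994 between the gamma_ON arrays and 0.986 between the gamma_OFF arrays. Between gamma_OFF replicate 1 and gamma_ON replicate 2 it was 0.987, and between groups it reached 0.988, between CTRL replicate 1 and gamma_ON replicate 2. Between 13 and 51 genes differed more than 2-fold within a replicate pair, against 85 to 379 between arrays of different groups. The first principal component held 52.1% of the variance. Gamma_OFF replicate 2 scored 35.3 on it and gamma_OFF replicate 1 scored 14.6, while the other arrays lay at -8.89 or below. Gamma_OFF replicate 2 also had the narrowest range of signal, with an SD over genes of 1.64 against 1.70 to 1.81 on the other arrays. The moderated F test called 1238 genes among the 3 groups. This count was 509 without gamma_OFF replicate 2, 4000 without gamma_OFF replicate 1, 319 without CTRL replicate 1, 253 without CTRL replicate 2, 253 without gamma_ON replicate 1 and 333 without gamma_ON replicate 2.

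**Figure D1:**
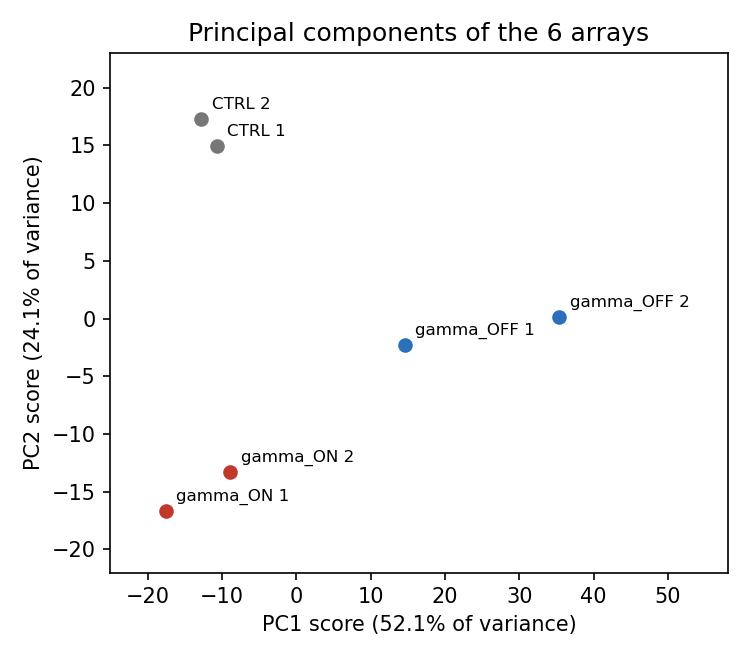
Scores of the 6 arrays on the first principal component (x axis, 52.1% of the variance) and the second (y axis, 24.1%), 1 point per array, coloured by group. Each group takes its own part of the plot, and gamma_OFF replicate 2 lies farthest along the first component, at 35.3.

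The comparison of gamma_ON with CTRL addressed what the vector with the phosphomimetic histone changed. CTRL carried eGFP alone and no group carried H2A.X without a substitution. An effect of S139E therefore cannot be told apart from one of added H2A.X. AFP, which encodes alpha-fetoprotein, rose 20.7-fold, from 6.90 ± 0.05 to 11.27 ± 0.14 (log2, mean ± SD of 2 arrays). Its log2 fold change was 4.37 (SE 0.14, adjusted p = 2.54e-06). AHSG, which encodes fetuin-A, rose by 3.41 (SE 0.17). The fibrinogen chain genes FGA, FGG and FGB rose by 3.10 (SE 0.17), 3.02 (SE 0.11) and 2.17 (SE 0.16), and the apolipoprotein gene APOB by 2.38 (SE 0.16). MIXL1, a homeobox gene of the primitive streak, rose by 1.94 (SE 0.17, adjusted p = 0.000866). GDF3, which encodes a TGF-beta family ligand, rose by 1.98 (SE 0.15), HAVCR1 by 2.07 (SE 0.17) and GSTA2, a glutathione transferase gene, by 2.00 (SE 0.23). GSTA2 had an adjusted p of 0.0568 without gamma_ON replicate 2.

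Among the genes that fell in gamma_ON, MRPL22, which encodes a protein of the mitochondrial ribosome, led with -3.63 (SE 0.16, adjusted p = 1.1e-05). GRPR, the receptor gene for gastrin-releasing peptide, changed by -1.94 (SE 0.16) on its brighter row and by 0.43 on its other row, so its rows disagree. CABYR stood at -1.52 (SE 0.13) and SYT11 at -1.13 (SE 0.11). DCC, a netrin receptor gene, stood at -1.43 (SE 0.17), GDF15, which encodes a stress-responsive cytokine, at -1.40 (SE 0.16), the noncoding RNA gene PURPL at -1.38 (SE 0.17) and UBAP2L at -1.22 (SE 0.13). Without gamma_ON replicate 1, DCC, GDF15 and PURPL had adjusted p-values of 0.0717, 0.0645 and 0.0779, and UBAP2L had 0.0513 without gamma_ON replicate 2. HSPA1B and HSPA1A, at -1.24 and -1.15, are near-identical heat shock genes, so their separate values are uncertain, and they had adjusted p-values of 0.0513 and 0.0619 without gamma_ON replicate 2.

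In all, 230 of 14884 genes were called, 110 higher and 120 lower. Of these, 69 changed at least 2-fold, 41 higher and 28 lower. All 230 had groups that did not overlap, a pattern that 52.4% of all genes showed and that chance gives in 33.3%. The count was 91 without CTRL replicate 1, 38 without CTRL replicate 2, 38 without gamma_ON replicate 1, 34 without gamma_ON replicate 2, and 487 without either gamma_OFF array. Of the 38 called genes that the naming rule takes, 14 were called whichever array was left out: AFP, AHSG, FGA, FGG, FGB, APOB, GDF3, MIXL1, HAVCR1, HAND1, MRPL22, GRPR, CABYR and SYT11.

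**Figure D2:**
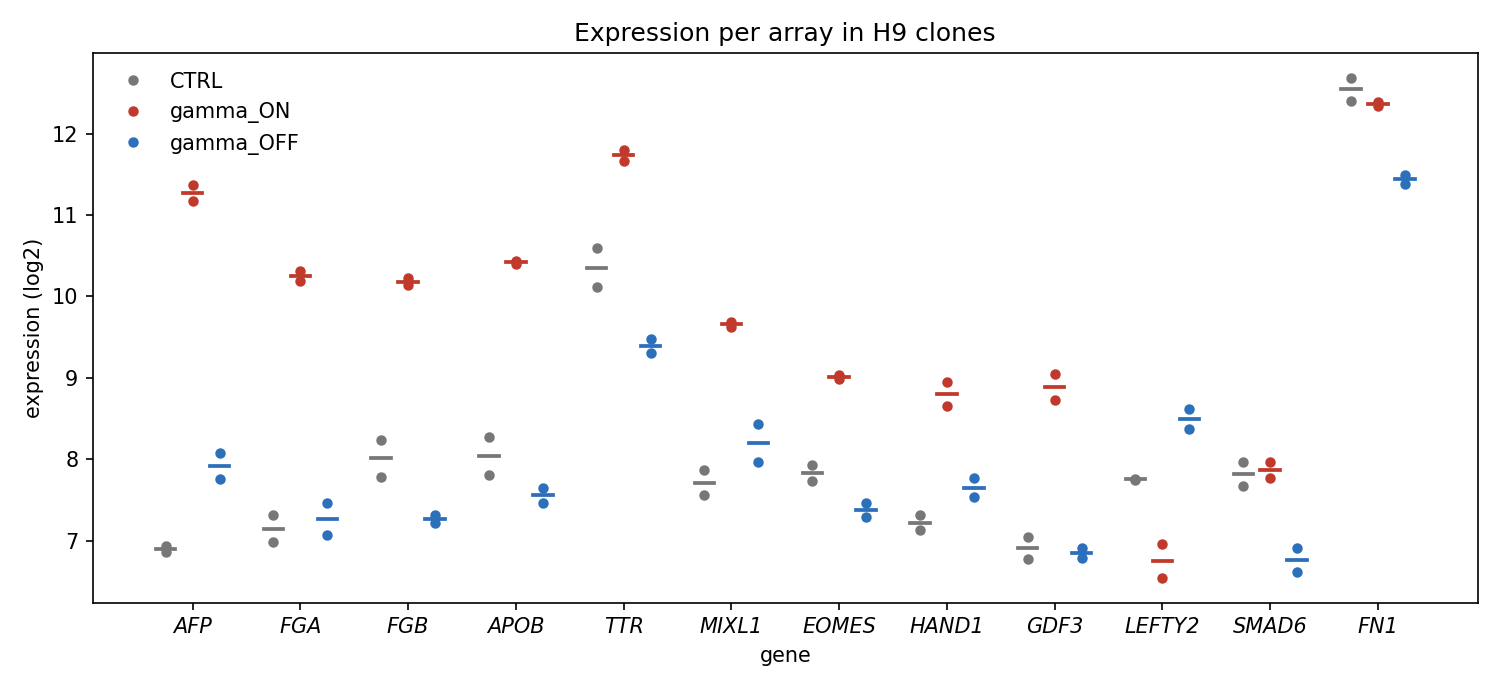
Expression (y axis, log2) of 12 genes (x axis) in the CTRL, gamma_ON and gamma_OFF arrays, with 1 point per array and a bar at the mean of each group. AFP lies at 11.27 on average in gamma_ON against 6.90 in CTRL and 7.92 in gamma_OFF, and LEFTY2 is lowest in gamma_ON, at 6.75, and highest in gamma_OFF, at 8.49.

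Camera called several lineage lists higher in gamma_ON at its preset correlation, and 0 lists with an estimated correlation. Of 16 measured endoderm genes, AFP, APOB, FGB, TTR (1.38, SE 0.17) and APOA2 (1.11, SE 0.17) rose, CXCR4 fell by 0.62 and 10 did not pass. Adjusted over the list alone, 5 rose and 1 fell. Of 19 primitive streak genes, MIXL1, APLNR (1.25, SE 0.17) and EOMES (1.18, SE 0.13), a T-box gene of mesendoderm, rose and 16 did not pass; 6 rose adjusted over the list alone. Of 12 cardiac mesoderm genes, HAND1 (1.59, SE 0.15), ISL1 (0.80, SE 0.13) and BMP4 (0.76, SE 0.12) rose and 9 did not pass, with 6 rising adjusted over the list alone. The dimmer row of ISL1 gave -0.02. By camera the adjusted p was 4.47e-05 for endoderm, 4.47e-05 for cardiac mesoderm and 0.00529 for primitive streak, and each list had an adjusted p = 0.598 with an estimated correlation. Without CTRL replicate 2, APLNR, ISL1 and BMP4 had adjusted p-values of 0.102, 0.2 and 0.205. EOMES had 0.0522 without gamma_ON replicate 1, and TTR and APOA2 had 0.0746 and 0.145 without gamma_ON replicate 2. CXCR4 had 0.288 without gamma_ON replicate 1.

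Camera called the neuroectoderm list lower in gamma_ON at its preset correlation, and not with an estimated one. Among its 24 genes ZIC1 fell by 0.64 (adjusted p = 0.0488, and 0.321 without CTRL replicate 1) and 23 did not pass, while 7 fell adjusted over the list alone. The camera adjusted p was 0.00286, with an adjusted p = 0.598 with an estimated correlation, and 0.0677 with dim genes left out.

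All 24 measured G1/S genes had a positive log2 fold change in gamma_ON, with a median of 0.46. Of these 0 were called by limma over all genes and 18 adjusted over the list alone. CDCA7 stood at 0.64 (SE 0.14, adjusted p = 0.0702) and GINS2, a replication fork gene, at 0.61 (SE 0.18, adjusted p = 0.158). All 26 G2/M genes were positive as well, with a median of 0.29. HMMR rose by 0.67 (adjusted p = 0.0243, and 0.23 without gamma_ON replicate 1), 25 did not pass, and 9 rose adjusted over the list alone. With camera the adjusted p was 1.34e-12 for G1/S and 1.41e-08 for G2/M, and both lists had an adjusted p = 0.598 with an estimated correlation. Of 21 double-strand break response genes 0 were called by limma over all genes and 0 adjusted over the list alone, with a median of 0.16. CLSPN stood at 0.58 (adjusted p = 0.0854) and ATR at 0.43 (adjusted p = 0.118). That list had a camera adjusted p of 0.0104, an adjusted p = 0.708 with an estimated correlation, 0.112 without CTRL replicate 1 and 0.112 without gamma_ON replicate 1.

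Of 29 measured pluripotency genes, GDF3, GAL (0.93), POU5F1 (0.71), VRTN (0.61) and LCK (0.57) rose, GRPR fell on its brighter row and 23 did not pass. Adjusted over the list alone, 7 rose and 2 fell. POU5F1, the gene of the core factor OCT4, has several near-identical pseudogenes, so its rise is uncertain (SE 0.14, adjusted p = 0.0441, and 0.283 without CTRL replicate 1). NANOG stood at 0.25 (SE 0.22, adjusted p = 0.654) and SOX2 at 0.24 (SE 0.12, adjusted p = 0.389). GAL and VRTN had adjusted p-values of 0.15 and 0.284 without gamma_ON replicate 1, and LCK had 0.348 without CTRL replicate 2. The list's camera adjusted p was 0.0445, with an adjusted p = 0.708 with an estimated correlation. It was 0.33 without CTRL replicate 1, 0.112 without gamma_ON replicate 1, 0.0502 without gamma_ON replicate 2, 0.0878 without either gamma_OFF array and 0.155 after rescaling of the signal range, an alternative chosen after the data were seen.

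The WNT, trophoblast and BMP lists were called higher in gamma_ON by camera at its preset correlation, and not with an estimated one. Of 17 WNT target genes DKK4 (1.18, SE 0.16) and BMP4 rose and 15 did not pass, with 5 higher and 1 lower adjusted over the list alone. Camera gave this list an adjusted p of 0.00982, with an adjusted p = 0.598 with an estimated correlation and 0.0638 without gamma_ON replicate 1. DKK4 itself had an adjusted p of 0.115 without gamma_ON replicate 1, and BMP4 0.205 without CTRL replicate 2. Of 11 trophoblast and amnion genes 0 were called by limma over all genes and 3 rose adjusted over the list alone. By camera the adjusted p was 0.0313, with an adjusted p = 0.598 with an estimated correlation, 0.148 without CTRL replicate 2 and 0.078 without gamma_ON replicate 2. Of 16 BMP target genes 0 were called by limma over all genes and 1 rose adjusted over the list alone. The camera adjusted p was 0.0313, with an adjusted p = 0.708 with an estimated correlation, 0.587 without CTRL replicate 2, 0.105 without gamma_ON replicate 1 and 0.0502 without gamma_ON replicate 2.

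The remaining lists that camera called in gamma_ON, at its preset correlation and not with an estimated one, were lower. Of 18 p53 target genes GDF15 fell and 17 did not pass, and 1 rose and 1 fell adjusted over the list alone. GDF15 had an adjusted p of 0.0645 without gamma_ON replicate 1. The list's camera adjusted p was 0.00878, with an adjusted p = 0.598 with an estimated correlation, 0.0805 without CTRL replicate 2 and 0.0772 without gamma_ON replicate 2. Of 15 imprinted genes DLK1 (-0.85) and KCNQ1OT1 (-0.81) fell and 13 did not pass, and 2 rose and 2 fell adjusted over the list alone. Camera gave this list an adjusted p of 0.0306, with an adjusted p = 0.598 with an estimated correlation, 0.152 without CTRL replicate 1 and 0.078 without gamma_ON replicate 2. DLK1 had an adjusted p of 0.132 without gamma_ON replicate 1 and KCNQ1OT1 had 0.205 without CTRL replicate 2. In the unfolded protein and integrated stress response list 0 of 16 genes were called by limma over all genes, with ATF3 at -0.58 (adjusted p = 0.0706). Adjusted over the list alone, 1 rose and 3 fell. By camera the adjusted p was 0.0101, with an adjusted p = 0.708 with an estimated correlation, 0.175 without CTRL replicate 2 and 0.0571 without gamma_ON replicate 2.

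In the mesenchymal list 0 of 11 genes were called by limma over all genes, with AXL at -0.49 (adjusted p = 0.0865), and 1 fell adjusted over the list alone. The camera adjusted p was 0.0306, with an adjusted p = 0.708 with an estimated correlation, 0.779 without CTRL replicate 1 and 0.078 without gamma_ON replicate 2. Markers of fibroblasts, the cell type of the feeder layer, were not called as a list (camera adjusted p = 0.657). Their 9 measured genes had a median of -0.16 and a mean of 0.01, which differ in sign. TAGLN fell by 0.62 (adjusted p = 0.0304, and 0.243 without CTRL replicate 2), 8 did not pass, and 2 rose and 1 fell adjusted over the list alone. In all, camera called 15 of 29 lists, 10 higher and 5 lower, against 8 without gamma_ON replicate 2. With dim genes left out 7 were called, and the adjusted p became 0.102 for pluripotency, 0.199 for WNT and for BMP targets, 0.0607 for the stress response list and 0.579 for imprinted genes. With an estimated correlation camera called 0, also 0 at an unadjusted p under 0.05, and fry's directional test called 0, against 8 unadjusted. Fry's test for change in either direction called 22.

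The comparison of gamma_OFF with CTRL addressed what the vector with the non-phosphorylatable histone changed. Here too, effects of T136A and S139A cannot be told apart from one of added H2A.X. More genes were called lower than higher, while the median log2 fold change over all genes was 0.01. MRPL22 again led, with -3.80 (SE 0.16, adjusted p = 2.2e-05). ZNF732, a zinc finger gene, stood at -1.96 (SE 0.14), FLRT3, which encodes a membrane protein that binds FGF receptors, at -1.71 (SE 0.13), and PURPL at -1.70 (SE 0.17). GDF15 stood at -1.47 (SE 0.16), UBAP2L at -1.44 (SE 0.13) and EDA2R, a TNF receptor family gene, at -1.41 (SE 0.12). The highest rise was that of CCDC152, by 3.40 (SE 0.22, adjusted p = 0.000498). CNTN1, which encodes a neural adhesion protein, rose by 1.26 (SE 0.16), QNG1 by 1.17 (SE 0.14) and AFP by 1.02 (SE 0.14). AFP had an adjusted p of 0.00743, and 0.0558 without CTRL replicate 2. SNAR-H, SNAR-B1, SNAR-C1 and SNAR-D, at 2.21, 1.86, 1.78 and 1.38, are near-identical copies of a small noncoding RNA gene, so their separate values are uncertain. SNAR-H had an adjusted p of 0.0976 without CTRL replicate 1 and SNAR-D had 0.0878 without CTRL replicate 2. The pseudogenes BCRP3 and SEPTIN7P14 stood at -1.88 (SE 0.48) and -1.52 (SE 0.29), and PCDH11X, a protocadherin gene, at -1.47 (SE 0.26). KRTAP2-2 rose by 1.26 (SE 0.23), ZNF727 by 1.13 (SE 0.19) and PNRC2 by 1.12 (SE 0.28). Without CTRL replicate 1, BCRP3 and KRTAP2-2 had adjusted p-values of 0.17 and 0.097. SEPTIN7P14, ZNF727 and PNRC2 had 0.116, 0.0941 and 0.185 without CTRL replicate 2, and PCDH11X had 0.0838 without gamma_OFF replicate 2.

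In gamma_OFF 1317 genes were called, 412 higher and 905 lower. The share called lower was 68.7%, against 57.3% at a threshold of 0.10 and 80.9% with dim genes left out. Of these, 140 changed at least 2-fold, 16 higher and 124 lower. All 1317 had groups that did not overlap, as 61.3% of all genes did, against 33.3% by chance. The fit shared 1 estimate of the spread, although the gamma_OFF replicates differed more than the others. With array weights 767 genes were called, against 803 in gamma_ON, and 567 against 487 in fits of only the 2 groups compared. The larger main count, 1317 against 230, therefore does not show a larger effect in gamma_OFF. Without gamma_OFF replicate 2, the array that stood apart, 389 genes were called, 88 higher and 301 lower, and 348 of them were among the 1317. The count was 3515 without gamma_OFF replicate 1, 189 without CTRL replicate 1, 131 without CTRL replicate 2 and 567 without either gamma_ON array. Of 67 called genes that the naming rule takes, 17 were called whichever array was left out, among them MRPL22, ZNF732, FLRT3, PURPL, GDF15, UBAP2L, EDA2R, CCDC152, CNTN1, QNG1, FN1, HOXA2, TP53INP1 and APOA2.

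Of 18 measured p53 target genes, 8 fell in gamma_OFF, 0 rose and 10 did not pass, and 10 fell adjusted over the list alone. GDF15 led, followed by TP53INP1 (-0.99, SE 0.13), PLK2 (-0.91, SE 0.13), which encodes a stress-responsive kinase, and SESN1 (-0.78, SE 0.13). The list's median was -0.32. Its camera adjusted p was 8e-05, with an adjusted p = 0.639 with an estimated correlation. PLK2 had an adjusted p of 0.0565 without CTRL replicate 1 and SESN1 had 0.107 without CTRL replicate 2. In the unfolded protein and integrated stress response list 5 of 16 genes fell, 11 did not pass and 7 fell adjusted over the list alone. VLDLR stood at -0.76 (SE 0.12) and DDIT3, which encodes the stress factor CHOP, at -0.75 (SE 0.17). Camera gave this list an adjusted p of 0.00543, with an adjusted p = 0.639 with an estimated correlation, 0.0648 after rescaling of the signal range and 0.225 with dim genes left out. VLDLR and DDIT3 had adjusted p-values of 0.111 and 0.186 without CTRL replicate 2.

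Of 11 mesenchymal genes, SNAI2 (-1.07, SE 0.16), VIM (-0.84, SE 0.12), which encodes vimentin, ZEB2 (-0.63, SE 0.14) and AXL (-0.55, SE 0.12) fell in gamma_OFF and 7 did not pass. Adjusted over the list alone, 5 fell. By camera the adjusted p was 0.00125, with an adjusted p = 0.639 with an estimated correlation. Camera called the fibroblast markers lower as well, and not with an estimated correlation. Of 9 measured, FN1, which encodes fibronectin (-1.11, SE 0.13), FBN1 (-1.02, SE 0.15) and TAGLN (-0.55, SE 0.11) fell and 6 did not pass, with 6 falling adjusted over the list alone. Their median was -0.44 and the camera adjusted p was 0.00608, with an adjusted p = 0.639 with an estimated correlation. Pluripotent cells also express FN1 and VIM. Without CTRL replicate 1, SNAI2, VIM, ZEB2, AXL and FBN1 had adjusted p-values of 0.052, 0.0743, 0.189, 0.167 and 0.0596. TAGLN had 0.143 without CTRL replicate 2.

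Of 16 BMP target genes 5 fell, 0 rose and 11 did not pass, and 5 fell adjusted over the list alone. SMAD6 (-1.05, SE 0.16) and BAMBI (-0.76, SE 0.13), which both encode inhibitors of BMP or TGF-beta signalling, were among them, as were GATA3 (-0.83, SE 0.13) and TBX3 (-0.75, SE 0.15). The list's median was -0.32 and its camera adjusted p was 0.00543, with an adjusted p = 0.639 with an estimated correlation and 0.176 without gamma_OFF replicate 1. Without CTRL replicate 1, SMAD6, BAMBI, GATA3 and TBX3 had adjusted p-values of 0.0643, 0.108, 0.0882 and 0.149. The cardiac mesoderm and primitive streak lists were not called in gamma_OFF (camera adjusted p = 0.0645 and 0.0718). Their medians of 0.37 and 0.19 were nonetheless positive, against 0.47 and 0.17 in gamma_ON. In each list 1 gene rose and 1 fell, and 10 of 12 and 17 of 19 did not pass. The endoderm list was not called (camera adjusted p = 0.0653). Of its 16 genes APOA2 (-1.24, SE 0.17), TTR (-0.96), FGB (-0.75) and GATA6 (-0.56) fell, AFP rose and 11 did not pass, and 1 rose and 5 fell adjusted over the list alone. AFP had an adjusted p of 0.0558 without CTRL replicate 2, and TTR, FGB and GATA6 had 0.087, 0.152 and 0.218 without CTRL replicate 1. The pluripotency list was not called (camera adjusted p = 0.0645), yet its median of 0.20 was close to the 0.15 of gamma_ON. Of its 29 genes 4 rose, among them LCK (0.84) and VRTN (0.68), 1 fell and 24 did not pass. Adjusted over the list alone, 6 rose and 2 fell. A rise of this list is therefore not particular to gamma_ON. POU5F1, NANOG and SOX2 stood at 0.36, 0.49 and 0.21, with adjusted p-values of 0.118, 0.163 and 0.25. In all, camera called 5 of 29 lists, all lower, against 12 without gamma_OFF replicate 2, 10 without CTRL replicate 1 and 9 without CTRL replicate 2, of which 2, 4 and 1 were higher. After rescaling of the signal range, and with dim genes left out, 8 were called, 4 of them higher. A repeated quantile normalization gave 10 with 4 higher, and averaged rows gave 10 with 3 higher. With an estimated correlation camera called 0, also 0 at an unadjusted p under 0.05, and fry's directional test called 0, against 8 unadjusted. Fry's test for change in either direction called 27.

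**Figure D3:**
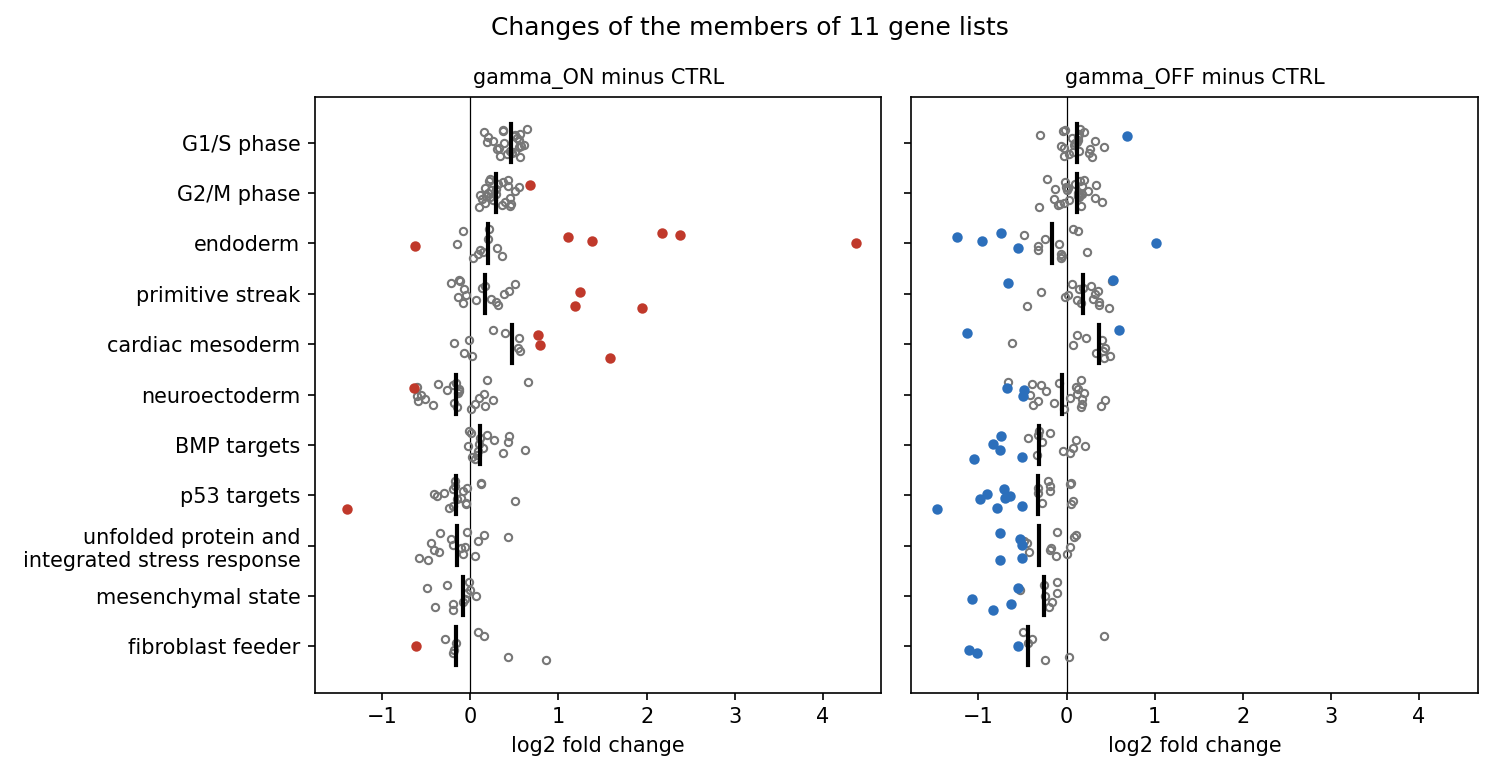
Log2 fold change (x axis) of each measured member of 11 gene lists (y axis), for gamma_ON minus CTRL on the left and gamma_OFF minus CTRL on the right. Filled points are genes called at an adjusted p under 0.05, open points are genes not called, black bars are list medians, and vertical position within a list carries no meaning; all G1/S genes lie above 0 on the left, and p53 targets centre on -0.32 on the right.

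The comparison of gamma_ON with gamma_OFF set both H2A.X vectors directly against each other. ZNF732 was higher in gamma_ON by 3.58 (SE 0.14, adjusted p = 7.25e-06) and AFP by 3.35 (SE 0.14, adjusted p = 9.15e-06). FGA, FGB, FGG, APOB and AHSG were higher by 2.99, 2.92, 2.87, 2.87 and 2.76. GSTA2 was higher by 2.49 (SE 0.23), APOA2 by 2.35 (SE 0.17) and TTR, which encodes the thyroxine carrier transthyretin, by 2.34 (SE 0.17). Lower in gamma_ON were CCDC152 (-2.84, SE 0.22), CABYR (-1.90, SE 0.13) and LEFTY2, which encodes an inhibitor of Nodal signalling (-1.74, SE 0.16, adjusted p = 0.000995). GRPR stood at -1.27 on its brighter row and at 0.69 on its other row, so its rows disagree. SNAR-F stood at -1.22, the pseudogene IGBP1P1 at -1.21, QNG1 at -1.16, KRTAP2-1 at -1.08, GPC4 at -1.02 and NPTX1 at -0.99. Without gamma_ON replicate 1, SNAR-F and KRTAP2-1 had adjusted p-values of 0.29 and 0.166. GRPR, IGBP1P1, QNG1, GPC4 and NPTX1 had 0.0622, 0.106, 0.0608, 0.0649 and 0.0686 without gamma_ON replicate 2.

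A total of 892 genes were called, 592 higher and 300 lower in gamma_ON. The split was 373 and 273 with arrays centred, 277 and 192 after a repeated quantile normalization and 250 and 177 after rescaling of the signal range. With dim genes left out it was 1219 and 276, where the median log2 fold change was 0.17, against 0.02 over all genes. Of these, 98 changed at least 2-fold, 84 higher and 14 lower. All 892 had groups that did not overlap, as 63.3% of all genes did, against 33.3% by chance. Without gamma_OFF replicate 2 the count was 150, 116 higher and 34 lower, and 133 of them were among the 892. It was 4061 without gamma_OFF replicate 1, 49 without gamma_ON replicate 1, 67 without gamma_ON replicate 2, 275 without either CTRL array and 427 after rescaling of the signal range. Of 57 called genes that the naming rule takes, 18 were called whichever array was left out, among them ZNF732, AFP, FGA, FGB, FGG, APOB, AHSG, GSTA2, APOA2, TTR, CCDC152, CABYR, LEFTY2, EOMES, APLNR, BAMBI, BMP5 and GDF3.

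Of 16 endoderm genes 6 were higher in gamma_ON, 0 were lower and 10 did not pass, with 7 higher adjusted over the list alone. The camera adjusted p was 0.000158, with an adjusted p = 0.625 with an estimated correlation. Of 16 BMP targets 6 were higher and 10 did not pass, with 9 higher adjusted over the list alone. BAMBI was higher by 1.38 (SE 0.13), TBX3 by 1.19 (SE 0.15), SMAD6 by 1.10 (SE 0.16) and GATA3 by 0.93 (SE 0.13). The list's camera adjusted p was 0.000158, with an adjusted p = 0.625 with an estimated correlation. TBX3, SMAD6 and GATA3 had adjusted p-values of 0.0919, 0.136 and 0.139 without gamma_ON replicate 1. The cardiac mesoderm list was not called (camera adjusted p = 0.185). Of its 12 genes 4 were higher and 8 did not pass, with 4 higher and 3 lower adjusted over the list alone. The primitive streak list was not called (camera adjusted p = 0.731), and its median of -0.06 and mean of 0.17 differ in sign. EOMES (1.64, SE 0.13), APLNR (1.54, SE 0.17) and MIXL1 (1.46, SE 0.17) were higher, RIPPLY2 was lower (-0.65) and 15 of 19 did not pass, with 5 higher and 2 lower adjusted over the list alone. Of 10 Nodal and TGF-beta target genes 5 were higher, among them GDF3 (2.04), BAMBI, FST (1.02) and NODAL (0.47). LEFTY2 and LEFTY1 (-0.77) were lower and 3 did not pass, with 5 higher and 2 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.169). Without gamma_ON replicate 1, MIXL1, RIPPLY2, FST, NODAL and LEFTY1 had adjusted p-values of 0.0622, 0.248, 0.116, 0.282 and 0.142.

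Of 24 G1/S genes TYMS, which encodes thymidylate synthase, was higher by 0.81 (SE 0.12, adjusted p = 0.0103, and 0.141 without gamma_ON replicate 1) and 23 did not pass. Adjusted over the list alone, 10 were higher, and the median was 0.36. Of 26 G2/M genes 0 were called by limma over all genes and 5 adjusted over the list alone, with a median of 0.23. Their camera adjusted p-values were 0.000912 and 0.00233, and both lists had an adjusted p = 0.625 with an estimated correlation. Both calls ended after rescaling of the signal range, at 0.185 and 0.638, after a repeated quantile normalization, at 0.106 and 0.381, and with dim genes left out, at 0.138 and 0.17. All 21 double-strand break response genes were positive, with a median of 0.36, and 0 were called by limma over all genes or adjusted over the list alone. TOPBP1 stood at 0.62 (adjusted p = 0.0748). Camera gave this list an adjusted p of 0.000257, with an adjusted p = 0.625 with an estimated correlation. Of 18 p53 targets TP53INP1 (0.83, SE 0.13) and SESN1 (0.54, SE 0.13) were higher and 16 did not pass, with 6 higher adjusted over the list alone. By camera the adjusted p was 0.00977, with an adjusted p = 0.625 with an estimated correlation, 0.0676 without gamma_OFF replicate 1 and 0.209 with dim genes left out. TP53INP1 and SESN1 had adjusted p-values of 0.153 and 0.298 without gamma_ON replicate 1.

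Of 9 fibroblast markers LUM (1.10, SE 0.20), FN1 (0.93, SE 0.13), FBN1 (0.82, SE 0.15) and LOX (0.57, SE 0.14) were higher in gamma_ON than in gamma_OFF and 5 did not pass, with 5 higher adjusted over the list alone. The camera adjusted p was 0.0183, with an adjusted p = 0.625 with an estimated correlation, 0.101 without gamma_OFF replicate 1 and 0.118 with dim genes left out. Without gamma_ON replicate 1 the adjusted p-values of LUM, FN1, FBN1 and LOX were 0.194, 0.134, 0.239 and 0.302. Camera called the germline and cancer-testis list lower, and not with an estimated correlation. TDRD1 was lower in gamma_ON than in gamma_OFF by 0.97 (SE 0.14, adjusted p = 0.0113). With 1 array left out its difference ranged from -1.14 to -0.80. The other 17 of 18 did not pass, with 1 lower adjusted over the list alone. Against CTRL, TDRD1 rose in gamma_OFF by 0.72 (adjusted p = 0.0217), and 0 genes of the list were called in gamma_ON. The list's median against CTRL was 0.18 in gamma_OFF (camera adjusted p = 0.0583) and -0.04 in gamma_ON. Camera gave this list an adjusted p of 0.00295, with an adjusted p = 0.625 with an estimated correlation, 0.116 after rescaling of the signal range and 0.188 after a repeated quantile normalization. NANOG, POU5F1 and SOX2 stood at -0.24, 0.35 and 0.03, with adjusted p-values of 0.448, 0.124 and 0.883. In all, camera called 8 of 29 lists, 7 higher and 1 lower. With dim genes left out 6 were called, 3 higher and 3 lower. With an estimated correlation camera called 0, also 0 at an unadjusted p under 0.05, and fry's directional test called 0, against 13 unadjusted. Fry's test for change in either direction called 28.

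Both mutant vectors were compared with the same CTRL arrays. Genes that fell under both included MRPL22, PURPL, GDF15, UBAP2L, DCC, DLK1, KCNQ1OT1, CCN2, VEGFA and GRPR, whose rows disagree in gamma_ON. Of these, MRPL22 alone was called in both comparisons whichever array was left out. GRPR, DLK1, KCNQ1OT1, CCN2 and VEGFA had adjusted p-values of 0.223, 0.0853, 0.0929, 0.0557 and 0.0873 in gamma_OFF without CTRL replicate 2, and DCC had 0.0517 there without gamma_OFF replicate 2. In gamma_ON, CCN2 had 0.0587 without CTRL replicate 2 and VEGFA had 0.284 without gamma_ON replicate 1. In all, 25 genes rose under both vectors, against 3.04 for independent lists of these sizes. Another 93 fell under both, against 7.30, and 9 were called in opposite directions. How many opposite calls independent lists would give was not computed, so these 9 are not shown to be an excess. Across genes, the log2 fold changes against CTRL correlated with r = 0.376. Unchanged groups set against shared simulated controls gave 0.50, with an SD of 0.00809 over 100 draws. The observed r was 0.25 without gamma_ON replicate 2. The covariance was 0.0321 against a simulated 0.0104, a difference of 0.0217. With gamma_ON set against 1 CTRL array and gamma_OFF against the other, a test chosen after the data were seen, r was 0.229 and 0.259 and the covariance 0.0217 and 0.0245 in the 2 assignments. Called this way, 2 and 0 genes rose under both vectors, against 0.0671 and 0.0524 for independent lists, and 6 and 14 fell under both, against 0.112 and 0.304. As each part held 1 CTRL array, part of the excess among the 25 and 93 genes may still come from the shared controls.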

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

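All tests of explanations in this part, and the rescaling of the signal range, were chosen after the results were seen. Among genes called in opposite directions against CTRL under the mutant vectors, gamma_ON minus gamma_OFF was 2.92 for FGB, 2.35 for APOA2 and 2.34 for TTR on the log2 scale. It was 3.58 for ZNF732, 2.19 for PRTG, 2.17 for MT1F, 1.88 for NTS and 1.86 for TMEM88. LEFTY2 went the other way, with -1.74. Picking genes called in opposite directions fixes that these differences are large, so their p-values add nothing. Of the 9 genes, ZNF732 alone was called in both comparisons with CTRL whichever array was left out.

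Array rows without a gene name, which the comparisons above do not use, also passed the threshold. Of 37519 such rows, 12 were called for gamma_ON against CTRL, 564 for gamma_OFF against CTRL, 34 higher and 530 lower, and 8 for gamma_ON against gamma_OFF. Their median level was 5.75, against 7.12 for the named genes.

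Of 17 measured genes of proteins secreted by liver, looked up after the first of them were seen to rise, 12 rose in gamma_ON and 5 did not pass, with a median log2 fold change of 1.38 (SD 1.35), and of 3.02 over 7 picked for their rise. The fibroblast feeder markers had a median of -0.158 with an SD of 0.434 over 9 genes. These are human array rows while the feeders were mouse cells, so the markers cannot decide whether feeder RNA contributed. The signal range of the gamma_ON arrays was hardly wider, with SDs over genes of 1.81 and 1.76, against 1.76 and 1.78 in CTRL. So small a difference argues against the range as the source of these rises. Rescaling could therefore change them little, and gave medians of 1.29 over the 17 and 2.95 over the 7. A share of differentiated endoderm cells in the culture stays open, since 7 endoderm transcription factor genes had a median of 0.108 with an SD of 0.170, which does not decide how large a share could go unseen. The vector stays open as well and is untested, because vector and clone cannot be separated here, and in gamma_OFF 4 of the 17 genes also rose and 3 fell.

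More genes were called lower than higher in gamma_OFF against CTRL, by a ratio of 2.20. Rescaling, which removes the narrower signal range of these arrays, gave a ratio of 2.22 over 932 calls. A repeated quantile normalization gave 327 higher and 613 lower. Over genes, gamma_OFF minus CTRL correlated with the mean level at r = -0.299, against 0.0719 for gamma_ON minus CTRL. Without gamma_OFF replicate 2, the array that stood apart, the ratio was 3.42. The share called lower also moved with the number of calls, from 68.7% to 57.3% at a threshold of 0.10. Neither the ratio after rescaling nor the ratio without that array can therefore decide whether range or array is the whole cause. The sizes varied, with 1255 higher and 1686 lower at a threshold of 0.10, 1407 and 2108 without gamma_OFF replicate 1, 426 and 679 with arrays centred and 246 and 1040 with dim genes left out, while the median log2 fold change over all genes was 0.01. No biological explanation was tested, and the vector stays open.

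Single genes lay far apart between vectors and close within them: MRPL22 stood at -3.72 and UBAP2L at -1.33 in the mutant groups minus CTRL. Gamma_ON minus gamma_OFF was 0.17 for MRPL22 and 0.22 for UBAP2L (limma adjusted p = 0.456 and 0.259). For both genes CTRL alone stood apart, so a fall in the mutant groups cannot be told from a high level in the CTRL samples. Their 20 nearest measured neighbours, pooled over both genes, had a median of 0.137 with an SD of 0.359. This argues against a loss of copies shared by both surrounding regions, while neither region was tested by itself. An event in the single gene stays open. Replicates that stem from 1 clone per vector also stay open: at most 1 gene differed 4-fold between replicates, against 4 to 23 between vectors, so a difference between clones cannot be told apart from an effect of the vector. No biological explanation was tested.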

How the results depend on the processing

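Rescaling of the signal range and separate controls for each mutant group were chosen after seeing the data. Among the alternatives for genes the naming rule takes, 5 values changed sign, each of a gene called neither before nor after; the cause was not tested. For gamma_ON against gamma_OFF, SOX2 went from 0.0269 to -0.0758 after a repeated quantile normalization and to -0.325 after rescaling. With 1 array left out it ranged from -0.0512 to 0.105 and NANOG from -0.563 to 0.0825, and CD34 ranged from -0.727 to 0.0358 for gamma_OFF against CTRL. Of 1200 values for gamma_ON against CTRL 1046 kept direction and side of the threshold, 78 lost the call and 76 gained it. For gamma_OFF against CTRL these were 932, 227 and 10 of 1170, and for gamma_ON against gamma_OFF 984, 213 and 29 of 1230. H2AX gave no value, since it was not analysed here. The other alternatives set beforehand for a result were run for it; none was set for gene lists under robust eBayes, fits of only the 2 groups compared, every row tested or array weights.

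Genes called with 1 array left out ranged from 34 to 487 for gamma_ON against CTRL, from 131 to 3515 for gamma_OFF against CTRL, from 49 to 4061 for gamma_ON against gamma_OFF and from 253 to 4000 among the 3 groups. Lists called ranged from 8 to 14, from 6 to 12 and from 7 to 10, and the correlation of the effects from 0.25 to 0.462. Leaving out an array lowers the degrees of freedom, and a lone array is assumed to vary like the others. For the further changes the cause was not tested. Separate controls, with 1 CTRL array for each mutant group, gave correlations of 0.229 and 0.259.

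An intensity trend gave 386 genes for gamma_ON against CTRL, 1628 for gamma_ON against gamma_OFF and 2046 among the groups. Fits of only the 2 groups compared gave 487, 567 and 275 genes. Array weights gave 803, 767 and 229. A threshold of 0.10 gave 508, 2941 and 3121, and 3369 among the groups, and a log2 fold change of at least 0.58 left 823 for gamma_OFF against CTRL; both follow from the threshold itself. With dim genes left out 1495 genes were called for gamma_ON against gamma_OFF, 7 lists for gamma_ON against CTRL and 8 lists for gamma_OFF against CTRL. Averaged rows gave 10 lists for gamma_OFF against CTRL. A repeated quantile normalization gave 469 genes for gamma_ON against gamma_OFF and 10 lists for gamma_OFF against CTRL. Rescaling gave 427 genes for gamma_ON against gamma_OFF, 811 among the groups and 8 lists for gamma_OFF against CTRL. Camera with an estimated correlation called 0, 0 and 0 lists, and fry's directional test 0, 0 and 0, against 8, 8 and 13 at an unadjusted p under 0.05.

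With the replicate block 210, 1245 and 871 genes and 1168 among the groups were called, with 15, 5 and 8 lists. What arrays with the same replicate number had in common is not stated in the sample descriptions. Deviations within groups correlated over genes with r between -0.0962 and 0.088, which shows no strong common deviation. Array signal over background limits what can be seen in dim genes.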

Other observations

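The tests of lists here were planned, and the naming rule takes GDF3 and CCN2 for gamma_ON and CCN2, BAMBI, HOXA2 and HOXB2 for gamma_OFF in these lists, while other genes and the values per chromosome were chosen after their values were seen. Of 10 Nodal and TGF-beta target genes, GDF3 (1.98) and NODAL (0.76) rose in gamma_ON against CTRL, CCN2 (-1.12), LEFTY2 and TAGLN (-0.62) fell and 5 did not pass, with 5 higher and 3 lower adjusted over the list alone. The list was not called (camera adjusted p = 0.786). In gamma_OFF, LEFTY2 (0.74) rose, 5 fell, among them CCN2 (-0.94) and BAMBI (-0.76), and 4 did not pass, with 3 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.209). In gamma_ON, NODAL and CCN2 had adjusted p-values of 0.169 and 0.0587 without CTRL replicate 2, and LEFTY2 had 0.136 without gamma_ON replicate 2. In gamma_OFF, LEFTY2 and CCN2 had 0.146 and 0.0557 without CTRL replicate 2, and BAMBI had 0.108 without CTRL replicate 1. Of 26 HOX genes 0 were called by limma in gamma_ON, also 0 adjusted over the list alone. In gamma_OFF HOXA2 (-1.31) and HOXB2 (-0.71) fell, HOXD9 (0.51) rose and 23 did not pass, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0645). HOXB2 had an adjusted p of 0.213 without CTRL replicate 1 and HOXD9 had 0.244 without CTRL replicate 2.

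Further genes of liver-type secreted proteins were looked up. ITIH2 rose in gamma_ON (adjusted p = 0.000191), as did APOC3, by 1.68 (SE 0.13), APOA4, by 1.34 (SE 0.12), and APOM, by 0.74 (SE 0.11, adjusted p 0.196 without CTRL replicate 2). ALB, the albumin gene, stood at 0.49 (SE 0.11, adjusted p = 0.0763), APOA1 at 0.20, TF, the transferrin gene, at 0.09, APOE at -0.18 and ITIH3 at -0.17, none of them called. In gamma_OFF, AFP (1.02), APOA4 (0.71), AHSG (0.65) and ITIH2 (0.59) rose as well, while APOA2, TTR and FGB fell. APOA4 and ITIH2 had adjusted p-values of 0.101 and 0.147 without CTRL replicate 1, and AFP and AHSG had 0.0558 and 0.27 without CTRL replicate 2. Over the 7438 genes at or above the median level, median log2 fold changes per chromosome ran from -0.02 to 0.09 for gamma_ON against CTRL and from -0.20 to 0.01 for gamma_OFF against CTRL, where an extra copy beside a pair would give 0.58 at full effect. With dim genes left out the median of gamma_OFF against CTRL was -0.10, against 0.01 over all genes, so the values per chromosome stand relative to that shift.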
